A study of Homo sapiens with 24 samples.

How the data were processed

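Transfer RNA libraries of HEK293T cells were made, per the labels' protocols, from gel-isolated tRNA with a small RNA library kit and with E. coli tRNA added. The labels placed the 24 libraries in 8 groups of 3, which were wild-type sets 1 and 2 and 2 clones each of the DUS1L, DUS2L and DUS3L knockouts. The submitters' processing notes name fastp, STAR, featureCounts and DESeq2 and the human build hg38 for the authors' processing, without versions or the step each tool served. Read trimming settings, the treatment of reads that match several tRNA genes and the method of scaling were not given in the sources used here. Modified bases can stop or misdirect reverse transcription in such libraries, and near-identical isodecoders share reads, so that isodecoder values depend on how reads were assigned.

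The authors' deposited tables held their own comparisons and no values per library. For each of 6 tables, per the file headers, they gave the mean of normalised counts (a signal never below 0), the log2 fold change and the p-value of clones #1 and #2 against wild type, besides fold and -log10 columns that repeat them. The p-values were the authors' and had not been adjusted. The headers do not say which labelled clone is #1, nor which wild-type set was used, so clones are named #1 and #2 here. The recovered wild-type levels showed that the DUS1L and DUS2L tables rest on the same wild-type libraries and the DUS3L table on others.

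From these values the following was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The authors' p-values were adjusted by the Benjamini-Hochberg method over every row with a p-value in a column, with a threshold of 0.05. Before the data were examined an adjusted p by the authors had been planned on, and this adjustment takes its place. The SE of a fold change was the fold change over the normal quantile of its p-value. The wild-type level was solved from the mean and both fold changes, assuming 3 libraries in each of 3 groups. The dispersion solved from clone #1 predicted the SE of clone #2 with a median log2 error of 0.000226 over 68 DUS1L anticodon families with a mean of at least 100. Of the recovered spread, the part from the wild type was used to simulate 1000 pairs of unchanged clones that share it, and 1000 sets of unchanged DUS1L and DUS2L clones. Clones were compared by the difference of their fold changes over the root of the summed squared SEs. For DUS2L clones against the wild type of the DUS3L table, the recovered levels were compared with the variances recovered from each table. A comparison of pooled clones was not run, since the tables keep clones apart.

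Lists fixed before the data were examined were the amino acid isotypes, class II tRNAs, the anticodon's starting base, mitochondrial tRNAs and Tyr-GTA alone (4 or 5 isodecoders, inside the central 95% in every clone, with medians from -0.42 to 2.18). Each median, over isodecoders with an authors' mean of at least 10 and at least 3 members, was placed among 10000 random lists of the same size matched on abundance in 5 bins, which describes these libraries and is no test. Lists by the presence of the modified uridines need a genome sequence and were not run. Named tRNAs follow a rule fixed beforehand. These are Tyr-GTA and iMet-CAT, up to 12 families and 10 isodecoders past the threshold in both clones in the same direction by the smaller change, the 4 of lowest p where fewer than 4 qualify, up to 3 members of each list outside the central 95% in both clones, and up to 4 tRNAs that passed in opposite directions, of which there were none. Those with a mean under 10 are not named. Alternatives were a stricter adjusted p of 0.01, an absolute log2 fold change of at least 1, a mean of at least 100, the spike-ins as reference, anticodon families in place of isodecoders, and 7 chosen after the data were seen.

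Genes were placed with RefSeq annotation of GRCh38, the build that the submitters' processing notes name as hg38, and overlapping genes with GENCODE. Of 261 nuclear entries 245 matched a RefSeq tRNA gene (17 in an exon and 54 in an intron of another gene), and the gene printed can stand for identical copies. The calling was tested on simulated tables of 257 DUS2L isodecoders, 10 tables with 200 changed isodecoders in all. Of these, both clones recovered 6.94% at 2-fold, 62.1% at 4-fold and 90% at 8-fold, with 0.9 false calls per table in clone #1, so that smaller changes are mostly missed at this spread. Here and in the test between clones, changes were planted only at a mean of at least 100. Each row was tested with the dispersion used to draw it. Recovery at lower means and false calls from an estimated dispersion were thus not measured. The test between clones, on isodecoders changed in clone #2 only, found 2.63% at 2-fold, 26% at 4-fold and 82.4% at 8-fold with 0 false calls, and 19.7%, 74% and 95.9% with 1.1 false calls per table once the shared wild-type spread was left out. Of 200 random lists of 15 unchanged isodecoders 4% lay outside the central 95%, and all 10 lists raised 2-fold did.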

Results

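Transfer RNA was sequenced from HEK293T cells, a human embryonic kidney line, in which the genes of the dihydrouridine synthases DUS1L, DUS2L or DUS3L had been knocked out. These enzymes reduce uridines of tRNA to dihydrouridine, DUS1L and DUS2L in the D loop and DUS3L in the variable loop. The 24 libraries fell into 8 groups of 3, made of 2 knockout clones for each of the 3 genes and 2 sets of wild-type cells. E. coli tRNAs for lysine, phenylalanine and tyrosine had been added as spike-ins. The authors' deposited tables gave, for clone #1 and clone #2 of each knockout, the fold change against wild type of 286 entries at the isodecoder level and of 74 at the anticodon level. The 286 were 261 nuclear entries, 22 mitochondrial tRNAs and the 3 spike-ins, and the 74 were 49 nuclear families with the same mitochondrial tRNAs and spike-ins. Isodecoders are tRNAs of distinct mature sequence that share an anticodon. The nuclear entries carried 260 isodecoder names, since tRNA-Asn-GTT-9-1 and tRNA-Asn-GTT-9-2 are by their names genes of 1 isodecoder. Their values still differed, with recovered wild-type levels of 2591 and 952 normalised counts for DUS1L, so their reads were assigned apart in a way not given. The question asked of each table was whether loss of the enzyme altered the abundance of particular tRNAs. Depth was known only as the authors' mean normalised counts, which summed to 1278870 per library in the DUS1L tables, 2649830 in the DUS2L anticodon table and 817514 in the DUS3L tables. Values per library were not analysed here, so every error below is the standard error (SE) recovered from the authors' fold change and p-value, and changes are given as log2 fold change ± SE. Adjusted p-values were computed from the authors' p-values by the Benjamini-Hochberg method, and a tRNA passed at an adjusted p under 0.05. The tables hold tRNA alone, so the level of the DUS messenger RNAs could not be used to check the knockouts. The labels do not say whether the 3 libraries of a clone came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

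In the DUS1L knockouts, 4 anticodon families were higher than wild type in clone #1 and 0 passed in clone #2. In the authors' deposited table, the leucine family Leu-CAA changed by 2.06 ± 0.44 in clone #1 (adjusted p = 0.00019), the selenocysteine tRNA SeC-TCA by 1.95 ± 0.46 (adjusted p = 0.000798), Leu-CAG by 1.77 ± 0.50 and Asn-GTT by 1.61 ± 0.45 (adjusted p = 0.0069 for both). For clone #2 the authors' deposited table held 0.90 ± 0.44, 1.21 ± 0.46, 0.68 ± 0.50 and -0.22 ± 0.45 for the same families, none past the threshold. The number of families with an unadjusted p under 0.05 was 11 in clone #1 and 9 in clone #2 of 70 tested in each. Tyr-GTA, the tyrosine tRNA, stood at 0.83 ± 0.45 and -0.35 ± 0.45 and the initiator tRNA iMet-CAT at 0.58 ± 0.43 and -0.05 ± 0.43 in the authors' deposited table, without passing in either clone.

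At the isodecoder level, 57 tRNAs passed in DUS1L clone #1 (43 higher, 14 lower) and 23 in clone #2 (7 higher, 16 lower). Both clones shared 4 higher and 8 lower isodecoders, where independent lists of these sizes would share 1.12 and 0.833, and unchanged clones set against the same wild-type libraries shared 0.003 on average in simulation. That simulation leaves out real effects, with which more rows can pass, so it sets no limit on calls shared through the wild type. Among the 12 isodecoders shared by both clones the deepest fall with a mean of at least 10 was that of tRNA-Asn-GTT-12-1, at -5.47 ± 0.72 and -7.99 ± 0.78 in the authors' deposited table, from a recovered wild-type level of 1150 normalised counts to 25.9 and 4.53. Another asparagine isodecoder, tRNA-Asn-GTT-10-1 (GRCh38 chromosome 1, 145129239 to 145129312), fell by 1.51 and 3.04 on the log2 scale in the authors' deposited table. Of the arginine isodecoders, tRNA-Arg-TCT-4-1 (chromosome 1, 159141611 to 159141684, in an intron of AIM2) stood at -2.80 ± 0.74 and -2.92 ± 0.74, and tRNA-Arg-TCG-4-1 at -2.50 ± 0.59 and -1.87 ± 0.59 in the authors' deposited table. Another arginine isodecoder, tRNA-Arg-CCT-2-1 (chromosome 17, 75034431 to 75034503, in an intron of KCTD2), fell from a recovered 15440 normalised counts to 3302 and 3868. The authors' deposited table also placed tRNA-Lys-CTT-4-1 at -1.69 ± 0.56 and -1.82 ± 0.56 and tRNA-Glu-TTC-3-1 at -1.42 ± 0.50 and -1.50 ± 0.49. Higher in both clones of the authors' deposited table were tRNA-Cys-GCA-17-1 (2.57 ± 0.43 and 1.48 ± 0.43), tRNA-Ser-TGA-1-1 (1.63 ± 0.43 and 1.43 ± 0.43), tRNA-Arg-CCG-1-1 (1.56 ± 0.47 and 1.85 ± 0.47) and, named after its values were seen, tRNA-Asp-GTC-3-1 (1.13 ± 0.41 and 1.25 ± 0.41). When each clone was centred on its median nuclear isodecoder, a shift of 0.19 in clone #1 and -0.18 in clone #2, the isodecoders shared by both clones were 8 higher and 6 lower, and the DUS1L calls of clone #2 were 18 higher and 13 lower. tRNA-Arg-CCT-2-1 and tRNA-Glu-TTC-3-1 then no longer passed in clone #2.

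Of the tRNA lists fixed beforehand, those outside the central 95% of random lists in both DUS1L clones depended on the lowest mean allowed. With a mean of at least 10 lysine tRNAs were the only such list of 25. With a mean of at least 100 these were leucine and class II tRNAs (leucine, serine and selenocysteine, which carry a long variable arm) of 24 lists. The 14 lysine isodecoders had a median of -0.84 in clone #1 (percentile 0.39), which turned to 0.30 (percentile 67) over the 12 with a mean of at least 100. In clone #2 it was -1.25 (percentile 0.02), and -1.18 (percentile 0.13) over the 12. The median and the calls had opposite signs in clone #1, where 6 lysine isodecoders were higher and 1 was lower (6 and 2 adjusted over the list alone), while in clone #2 none was higher and 4 were lower (6 adjusted over the list alone). Of the most abundant members in the authors' deposited table, tRNA-Lys-TTT-3-3 stood at -1.17 ± 0.62 and -1.30 ± 0.62 and tRNA-Lys-CTT-1-2 at -0.81 ± 0.50 and -1.30 ± 0.50, neither past the threshold, and tRNA-Lys-CTT-2-1 at -0.88 ± 0.46 and -1.80 ± 0.46, which passed in clone #2 only (adjusted p = 0.00257). Methionine, valine and anticodons starting with T were at low percentiles in clone #1 only (2.06, 1.46 and 0.205), valine no longer so with a mean of at least 100 (3.87), and alanine at percentile 100 in clone #2 only. The 22 mitochondrial tRNAs had medians of 0.64 and 0.08, with none past the threshold in either clone and percentiles of 98 and 92.1 (94.8 in clone #1 with a mean of at least 100). Class II tRNAs had medians of 0.75 and -0.11 (percentiles 92.8 and 40.9). Over the 21 with a mean of at least 100 these were 1.31 and 0.73 (percentiles 99.9 and 99.1). Of the 21, 10 were higher in clone #1 and 1 in clone #2 (5 after centring), and 0 were lower in either. Leucine tRNAs went from 0.95 and 0.24 (percentiles 95.8 and 85) to 1.71 and 0.79 (percentiles 99.9 and 98.2). Of these 12, 7 were higher in clone #1 and 0 passed in clone #2 (2 adjusted over the list alone, 3 after centring). The leucine families of highest recovered wild-type level, Leu-AAG (13669) and Leu-TAG (4682), were named after their values were seen. They stood at -0.89 and -0.88 and at -0.88 and -1.10 in the authors' deposited table. Neither carried a p-value, so neither could be called lower. Leu-CAA, Leu-CAG and Leu-TAA were above 0 in both clones. Every other list tested in DUS1L with a mean of at least 10 lay inside in both clones. By chance alone 1.25 of 25 lists would fall outside, against 5 in clone #1 and 2 in clone #2, and 1.2 of 24 with a mean of at least 100, against 4 in each clone.

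With the wild type of each deposited comparison, the DUS2L knockouts differed in the largest number of tRNAs. That order depended on the wild type. Against the recovered wild type of the DUS3L table, centred, 24 families and 76 isodecoders passed in both DUS1L clones. For both DUS2L clones these were 13 and 42. Of 71 anticodon families tested, 25 passed in clone #1 (6 higher, 19 lower) and 30 in clone #2 (12 higher, 18 lower), and 19 passed in the same direction in both, 6 higher and 13 lower, the E. coli tyrosine spike-in being 1 of the 13. Independent lists would share 1.01 higher and 4.82 lower families, and unchanged clones shared 0.002 on average in simulation. As for DUS1L, that simulation leaves out real effects and sets no limit on calls shared through the wild type. In the authors' deposited table, the serine family Ser-GCT stood at -2.86 ± 0.72 and -3.08 ± 0.72, SeC-TCA at -2.14 ± 0.49 and -2.58 ± 0.49, Leu-CAG at -2.31 ± 0.48 and -2.02 ± 0.48, and Leu-CAA at -1.71 ± 0.44 and -1.88 ± 0.44. Asn-GTT was at -2.34 ± 0.41 and -1.86 ± 0.41, Pro-AGG at -2.03 ± 0.57 and -2.08 ± 0.57, Ala-TGC at -1.95 ± 0.53 and -1.37 ± 0.53 and Arg-TCT at -1.71 ± 0.50 and -1.33 ± 0.50 in the authors' deposited table. Among mitochondrial tRNAs of the authors' deposited table, proline TGG (MT-TP, positions 15956 to 16023) rose by 1.62 ± 0.45 and 1.73 ± 0.45 and serine TGA (MT-TS1, 7446 to 7514) by 1.45 ± 0.53 and 1.42 ± 0.53, while aspartate GTC (MT-TD, 7518 to 7585) stood at -1.43 ± 0.55 and -1.34 ± 0.55.

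Tyr-GTA was higher in both DUS2L clones of the authors' deposited table, at 1.14 ± 0.43 (adjusted p = 0.031) and 1.87 ± 0.42 (adjusted p = 0.000157). Its isodecoders moved both ways, 2 higher and 2 lower in both clones (3 and 1 in clone #1 after centring). tRNA-Tyr-GTA-9-1, with a recovered level of 0.402 in wild type, held 1126 and 1344 of the family's 2183 and 3618 normalised counts. The family was also summed without isodecoders of a wild-type level under 10, a choice made after the data were seen, which leaves out what rose from low levels. It then went from 978.1 to 1049 and 2269 normalised counts, a log2 change of 0.10 and 1.21 without a test. iMet-CAT was at 0.09 ± 0.44 and 1.22 ± 0.44 in the authors' deposited table and passed in clone #2 only (adjusted p = 0.0187). Tyr-ATA, whose gene lies on chromosome 2 at 218245826 to 218245918 in an intron of ARPC2, had a recovered wild-type level of 0.402 normalised counts and 292 and 426 in the clones, so that no fold is given. The wild type of the DUS3L table held 118 for Tyr-ATA, of 509952 normalised counts in all. Wild-type cells thus also held this tRNA. The tables were scaled separately, and the totals of the DUS2L clones were 2011050 and 2833410. The median nuclear family lay at -1.10 in clone #1 and -0.45 in clone #2, and the mean of the spike-ins at -0.27 and -0.46. With each clone centred on the median nuclear family, 15 families were higher and 3 lower in both clones (19 and 3 in clone #1, 15 and 8 in clone #2), and with the spike-ins as reference 7 were higher and 6 lower (7 and 9 in clone #1, 15 and 8 in clone #2). After centring, iMet-CAT stood at 1.19 in clone #1 and passed there as well. Asn-GTT (-1.24 and -1.41), Leu-CAG (-1.21 and -1.57) and Ser-GCT (-1.77 and -2.63) were the families lower in both clones after centring on the median nuclear family.

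Among DUS2L isodecoders, 149 passed in clone #1 (46 higher, 103 lower) and 144 in clone #2 (59 higher, 85 lower), and 120 passed in the same direction in both (46 higher, 74 lower), the tyrosine spike-in among the lower in each case. Independent lists would share 9.87 higher and 31.8 lower. With each clone centred on the median nuclear isodecoder the shared calls were 69 higher and 25 lower (72 and 29 in clone #1, 74 and 51 in clone #2), and with the spike-ins as reference 49 higher and 40 lower (49 and 71 in clone #1, 74 and 51 in clone #2). Of the 44 nuclear isodecoders higher in both clones with a mean of at least 10, 19 had a recovered wild-type level under 10 normalised counts. tRNA-Gly-CCC-3-1 (chromosome 17, 19860862 to 19860932, in an intron of ULK2) rose from a recovered 103 normalised counts in wild type to 17000 and 32850, a change of 7.37 ± 0.63 and 8.32 ± 0.63 in the authors' deposited table. tRNA-Lys-CTT-10-1 rose from 4.29 to 1557 and 2464, and tRNA-Cys-GCA-11-1, tRNA-Cys-GCA-19-1, tRNA-Gln-CTG-7-1 and tRNA-Leu-CAA-5-1 from recovered levels near 1.45 to between 78.9 and 373. Besides tRNA-Tyr-GTA-9-1, tRNA-Ala-AGC-16-1 and tRNA-Lys-TTT-11-1 were under 1 in wild type and at 38.7 to 61.1 in the clones.

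Of 26 lists tested in DUS2L, 6 lay outside the central 95% of random lists in each clone, where 1.3 are due to chance, and 3 did so in both clones. Class II tRNAs were low, with a median of -1.48 in clone #1 (percentile 0.91, 5 higher and 16 lower of 36) and -1.90 in clone #2 (percentile 0, 6 higher and 20 lower). Adjusted over the list alone, 16 class II isodecoders were lower in clone #1 and 21 in clone #2, and after centring 9 were higher and 7 lower in clone #1 and 7 higher and 17 lower in clone #2. Asparagine tRNAs had medians of -1.74 and -1.99 (percentiles 1.28 and 0.015), with 12 of 17 lower in clone #1 and 11 in clone #2, the same numbers when adjusted over the list alone, and with 7 and 10 lower after centring. In the authors' deposited table tRNA-Asn-GTT-24-1 was at -3.91 ± 0.53 and -3.52 ± 0.53, tRNA-Asn-GTT-9-1 at -1.78 ± 0.44 and -1.99 ± 0.44, and tRNA-Asn-GTT-3-1 at -1.61 ± 0.46 and -0.93 ± 0.46, the last past the threshold in clone #1 only. The calls of tRNA-Asn-GTT-9-1 and tRNA-Asn-GTT-3-1 in clone #1 ended after centring. Summed with tRNA-Asn-GTT-9-2, the gene of the same name, tRNA-Asn-GTT-9-1 stood at -2.10 and -2.26 without a test, a sum chosen after the data were seen. Glycine tRNAs were high, with medians of 0.67 and 0.89 (percentiles 99.8 and 99.4), 5 of 12 higher and 2 lower in clone #1 and 6 higher and 2 lower in clone #2, the same adjusted over the list alone, and 7 higher and none lower in either clone after centring. The most abundant of them, tRNA-Gly-GCC-1-2, was at 1.03 ± 0.58 and 1.90 ± 0.58 in the authors' deposited table and passed in clone #2 only, whereas tRNA-Gly-CCC-2-1, at -1.05 ± 0.57 and -0.37 ± 0.57, passed in neither. The most abundant class II isodecoders in the authors' deposited table were tRNA-Leu-AAG-2-4, at -1.70 ± 0.80 and -1.99 ± 0.80 and past the threshold in clone #2 only, where centring ended the call, tRNA-Leu-TAG-2-1, which carried no p-value, and tRNA-Leu-TAG-3-1, at -1.40 ± 0.77 and -1.58 ± 0.77 and past it in neither. Alanine (percentile 0.235), arginine (0.775) and mitochondrial tRNAs (97.9) lay outside in clone #1 only, and leucine (0.295), serine (0.04) and tyrosine (97.7) in clone #2 only. With a mean of at least 100 serine lay inside (3.33). The 4 tyrosine isodecoders left, 3 higher and 1 lower in each clone, then lay outside in both (99.7 and 99.8). Of these, tRNA-Tyr-GTA-9-1 and tRNA-Tyr-ATA-1-1 had almost no counts in the wild type of the DUS2L table and reached that mean only through the DUS2L clones. The filter thus kept them because they were high there, and these percentiles give no further support. The mitochondrial median was -0.35 in clone #1, with 2 higher and 5 lower (2 and 1 adjusted over the list alone), but 0.65 after centring, with 5 higher and 0 lower. In clone #2 it was -0.83 (percentile 32.1, 2 higher and 7 lower, 2 and 4 adjusted over the list alone, and 4 and 1 after centring). The lists by the anticodon's starting base and the other lists tested lay inside in both DUS2L clones.

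In the DUS3L knockouts, 2 abundant anticodon families rose in both clones. Glu-TTC stood at 1.40 ± 0.29 and 1.38 ± 0.29 in the authors' deposited table (adjusted p = 0.000158 and 0.000219) and Gly-GCC at 1.38 ± 0.33 and 1.27 ± 0.33 (adjusted p = 0.00119 and 0.00236). Gly-GCC alone made up 64.2% of the authors' mean counts in this table. Its share of human tRNA counts also differed between wild-type libraries, at 52% in this table and 7.65% in the DUS1L table. After centring on the median nuclear family, which lay at -0.19 in clone #1 and 0.28 in clone #2, Gly-GCC stood at 0.99 in clone #2 and no longer passed there. Named after their values were seen, 4 families were lower in clone #1 only in the authors' deposited table, namely Val-TAC (-1.42 ± 0.40), Thr-AGT (-1.26 ± 0.35), Lys-TTT (-1.10 ± 0.35) and Ile-AAT (-1.09 ± 0.30), and 3 families were higher and 3 lower in clone #1 after centring. Gly-CCC (1.57 ± 0.37, adjusted p = 0.000765) and Asn-GTT (1.54 ± 0.39, adjusted p = 0.00189) were higher in clone #2 only, against 0.64 ± 0.37 and -0.09 ± 0.39 in clone #1 of the authors' deposited table. Tyr-GTA (0.07 ± 0.29 and 0.01 ± 0.29) and iMet-CAT (-0.42 ± 0.34 and 0.13 ± 0.34) passed in neither clone of the authors' deposited table. Unadjusted p-values under 0.05 numbered 15 in clone #1 and 8 in clone #2 of 74 families.

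At the isodecoder level, 22 passed in DUS3L clone #1 (7 higher, 15 lower) and 33 in clone #2 (30 higher, 3 lower), with 7 higher and 3 lower in both. Independent lists would share 0.755 higher and 0.162 lower. Centred on the median nuclear isodecoder, the calls of clone #1 were 12 higher and 10 lower. The 7 included the main members of the risen families in the authors' deposited table, tRNA-Glu-TTC-2-2 (1.47 ± 0.32 and 1.35 ± 0.32), tRNA-Glu-TTC-1-1 (1.24 ± 0.33 and 1.45 ± 0.33), tRNA-Gly-GCC-1-2 (1.38 ± 0.36 and 1.27 ± 0.36) and tRNA-Gly-GCC-4-1 (1.47 ± 0.38 and 1.48 ± 0.38). Of the isodecoders shared by both clones, the largest changes in the authors' deposited table were those of tRNA-Ile-AAT-2-1 (chromosome 6, 27688188 to 27688261), at 4.66 ± 1.12 and 6.74 ± 1.12, tRNA-Val-AAC-1-1, at 3.32 ± 0.83 and 6.50 ± 0.82, and tRNA-Asn-GTT-9-2, at 2.90 ± 0.57 and 4.11 ± 0.57, from recovered wild-type levels of 8.79, 3.41 and 31.7 normalised counts. Summed with tRNA-Asn-GTT-9-1, a choice made after the data were seen, the last stood at 0.53 and 1.94 without a test, as tRNA-Asn-GTT-9-1 was at -1.24 ± 0.44 and 0.65 ± 0.43 in the authors' deposited table and passed in neither clone. Lower in both clones of the authors' deposited table were tRNA-Thr-AGT-4-1 (-2.54 ± 0.63 and -2.34 ± 0.65), tRNA-Lys-TTT-1-1 (-1.86 ± 0.57 and -1.75 ± 0.58) and tRNA-Thr-TGT-3-1 (-1.20 ± 0.40 and -1.81 ± 0.40), whose call in clone #1 ended after centring. No list lay outside the central 95% of random lists in both DUS3L clones. In clone #1 this held for glutamine (percentile 1.17) and glutamate (98.4), and in clone #2 for asparagine (99.8), valine (97.6), class II (98.7) and anticodons starting with A (1.25). With a mean of at least 100, valine (85.5) and class II (92.2) lay inside in clone #2 and anticodons starting with G outside (99.9). Class II was at percentile 39.2 in clone #1, and mitochondrial tRNAs, with medians of 0.15 and 0.12 (-0.08 in clone #2 after centring), were at 85.5 and 16.6.

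**Figure D1:**
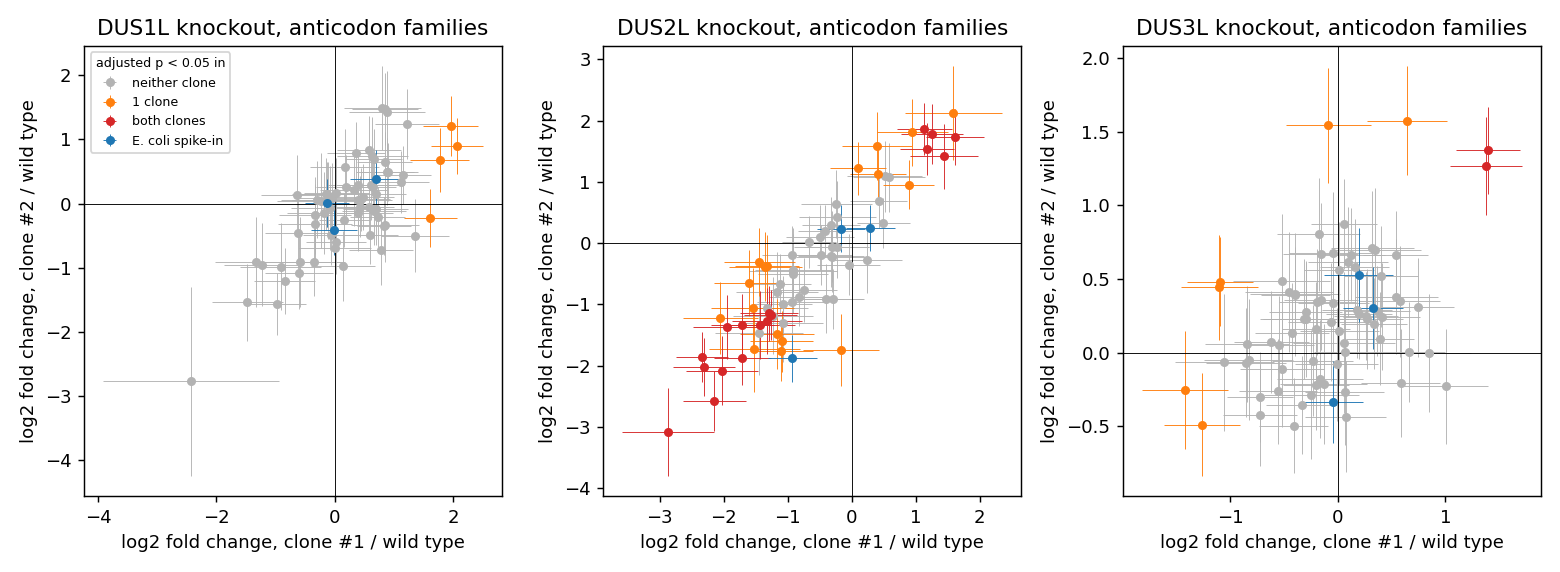
Log2 fold change of each anticodon family in clone #2 (vertical) against clone #1 (horizontal) for the 3 knockouts, with bars of 1 recovered SE, coloured by the clones in which the adjusted p passed 0.05, and E. coli spike-ins in blue. Families with a recovered wild-type level under 1 are left out. The DUS2L clones share 6 higher families, of which Tyr-ATA is not drawn, and 13 lower, the tyrosine spike-in included (15 and 3 after centring on the median nuclear family), the DUS3L clones 2 higher (1 after centring), and the DUS1L clones none.

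Across nuclear and mitochondrial isodecoders, the fold changes of the clones of a knockout had a correlation of 0.71 for DUS1L, 0.97 for DUS2L and 0.57 for DUS3L (Spearman's rho 0.69, 0.93 and 0.53), where clones without any change would give 0.49, 0.56 and 0.51 through the shared wild type. Across anticodon families the correlations were 0.73, 0.96 and 0.43 (rho 0.63, 0.87 and 0.36) against 0.50, 0.54 and 0.50. The DUS3L clones thus lay below the value for unchanged clones at that level, and their covariance was 0.11 against 0.07. tRNAs are not independent replicates, so these describe the tables. The covariances were 1.14, 6.40 and 0.79 against simulated values of 0.19, 0.22 and 0.13. For DUS2L, 19 of the 44 nuclear isodecoders higher in both clones had a recovered wild-type level under 10. They met the mean of at least 10 through the clones. Their large changes can raise the DUS2L correlation and covariance, and the simulation leaves this selection out. Part of the agreement may come from the shared wild type, whose libraries could not be split here. The clones themselves differed, by a test of the difference with adjustment over all isodecoders, at 0 isodecoders in DUS1L (37 at an unadjusted p under 0.05), 1 in DUS2L (tRNA-Asn-GTT-8-1, named after its value was seen) and 7 in DUS3L. At the family level this held for 0 families in DUS1L and 0 in DUS2L (2 and 0 at an unadjusted p under 0.05), and for Ile-AAT in DUS3L. That test counts the spread of the shared wild type and so errs towards few calls. With that spread removed, 40, 5 and 33 isodecoders differed, mostly one way in each knockout. Of the 40 in DUS1L 39 were lower in clone #2, of the 5 in DUS2L 4 were higher and of the 33 in DUS3L 32 were higher. The 4 in DUS2L included tRNA-Tyr-GTA-9-1 (0.26 ± 0.03) and tRNA-Tyr-ATA-1-1 (0.54 ± 0.06), which had almost no counts in the wild type of that table. Their recovered errors were counting error alone, so these calls may overstate the difference between the DUS2L clones. The median nuclear isodecoder differed between the clones by -0.37, 0.53 and 0.38. With each clone centred on it, a choice made after the data were seen, 12 differed in DUS1L (11 lower in clone #2), 6 in DUS2L, where the direction turned to 0 higher and 6 lower, and 30 in DUS3L (23 higher, 7 lower). With that spread counted, the centred test kept 0, 1 and 7 isodecoders and no longer called Ile-AAT.

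Between knockouts, mean fold changes correlated weakly across isodecoders, at 0.24 for DUS1L and DUS2L, 0.18 for DUS1L and DUS3L and -0.15 for DUS2L and DUS3L (Spearman's rho 0.13, 0.22 and -0.04). Over the pairs of single clones they ran from 0.20 to 0.24, from -0.02 to 0.34 and from -0.28 to 0.04, so that the sign of both pairs with DUS3L turned with the clones chosen. For DUS1L and DUS2L, whose tables share their wild type, the covariance of 0.54 included 0.18 from that sharing, and unchanged clones would correlate at 0.65 in simulation. With a mean of at least 100 the correlation was 0.22 for DUS1L and DUS2L and 0.27 for DUS1L and DUS3L, the reverse order. Across anticodon families these stood at -0.05 and 0.17. The value of -0.15 for DUS2L and DUS3L was -0.12 with a mean of at least 100 and -0.0058 across families. Called in both clones of both, 1 isodecoder was higher and 6 were lower in DUS1L and DUS2L, where independent lists would share 0.684 and 2.2. In 1000 simulations of unchanged clones against the shared wild type 0 such calls were shared. The simulation leaves out real effects and the independent lists leave out the shared wild type, so part of the excess may come from that sharing. The higher one was tRNA-Ser-TGA-1-1, and the 6 lower isodecoders included tRNA-Asn-GTT-12-1, tRNA-Asn-GTT-10-1 and tRNA-Arg-CCT-2-1, while tRNA-Arg-CCG-1-1 was higher in DUS1L and lower in DUS2L, where 2.47 such opposite calls are due to independent lists. DUS1L and DUS3L shared 0 calls in both clones. DUS2L and DUS3L shared 1 higher (tRNA-Gly-GCC-4-1) and 2 lower isodecoders (tRNA-Lys-TTT-1-1 and tRNA-Thr-AGT-4-1), against 1.18 and 0.813, and tRNA-Asn-GTT-9-2, whose change in DUS3L was smaller when summed with tRNA-Asn-GTT-9-1, and tRNA-Val-AAC-1-1 were called in opposite directions, against 2.40.

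The wild-type levels recovered from the DUS1L and DUS2L tables agreed to an SD of 0.02 log2 units over 69 anticodon families once a constant offset of 1.18 was removed, which is a difference in scaling. Those of the DUS3L table differed from them with an SD of 1.36. The wild-type cells of the DUS3L table held 52% of their human tRNA counts in Gly-GCC and 6.46% in mitochondrial tRNAs, against 7.65% and 16.6% in the DUS1L table. The DUS2L clones held 22.7% and 29.1% in Gly-GCC, and the DUS1L clones 7.56% and 5.94%. The tables were scaled separately, and these shares were not tested across them. Over 70 anticodon families the mean DUS2L change had a correlation of 0.62 (Spearman's rho 0.56) with the difference between the wild type of the DUS3L table and the DUS1L knockouts, 2 sets of libraries that enter no DUS2L comparison. Both were centred on the median nuclear family. Each DUS2L clone was also set against the recovered wild type of the DUS3L table, centred in the same way, a comparison chosen after the data were seen. Of 108 isodecoders called in both clones with their own wild type at the authors' scaling, 17 passed in the same direction in both clones (2 higher, 15 lower) and 10 in the opposite direction. With their own wild type centred as well, 11 of 86 passed in the same direction (3 higher, 8 lower) and 6 in the opposite direction. The SD of the log2 difference over 244 isodecoders was 1.27 and 1.34, against 2.47 and 2.61 with their own wild type. tRNA-Gly-CCC-3-1 stood at 0.48 ± 0.49 and 0.94 ± 0.49 and Tyr-GTA at 0.13 ± 0.36 and 0.12 ± 0.36 in that comparison, without passing. Of 18 families called in both clones at the authors' scaling, 4 stayed lower, namely Leu-CAA, Leu-CAG, SeC-TCA and Ser-GCT, named after their values were seen, and 3 passed in the opposite direction. With their own wild type centred as well, 2 of 18 stayed lower and 4 passed in the opposite direction. Of the 15 isodecoders that stayed lower from calls at the authors' scaling 13 were class II tRNAs.

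**Figure D2:**
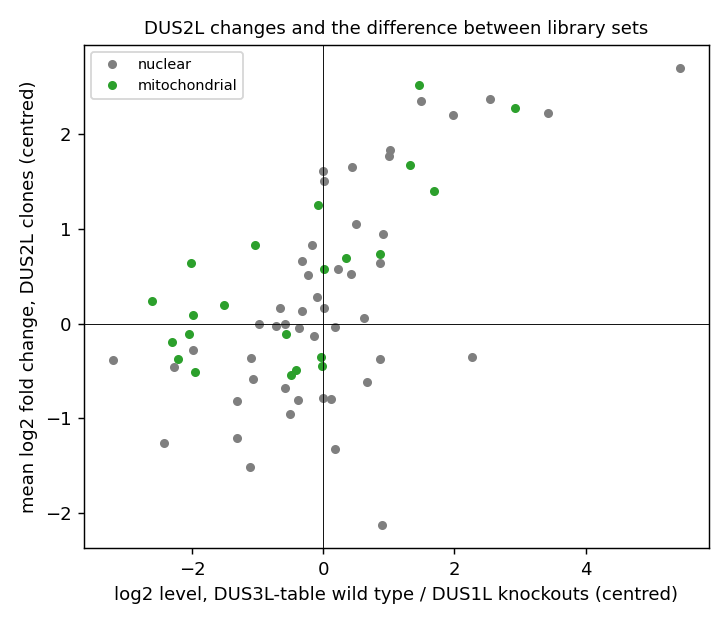
Mean log2 fold change of the DUS2L clones against wild type (vertical) against the log2 ratio of the wild type of the DUS3L table to the DUS1L knockouts (horizontal), each centred on the median nuclear family, with 1 point per anticodon family. The points rise from lower left to upper right, with a correlation of 0.62 over 70 families.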

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

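The tests of the library set, of the wild type of the DUS3L table, of loss of DUS2L and of reads moving between isodecoders, and the reference without the tyrosine spike-in, were chosen after the result or a closely related one was seen. Those of scaling, spike-ins and the gene cluster were chosen before that result was seen. Centring on the median nuclear tRNA, which the test of scaling uses, was itself chosen after the data were seen. A test for single outlying libraries and a count of other splits of the libraries need values per library and were not run.

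The clones of DUS3L differed at 7 isodecoders and 1 anticodon family, by the test of the difference itself. Clone #2 minus clone #1 on the log2 scale was 6.11 for tRNA-Thr-CGT-3-1, 5.77 for tRNA-Asn-GTT-25-1, 5.57 for tRNA-Ile-AAT-3-1, 4.23 for tRNA-Leu-AAG-1-2, 2.96 for tRNA-Lys-TTT-7-1, 2.91 for tRNA-Asn-GTT-6-1 and 2.19 for tRNA-Lys-TTT-6-1, and 1.58 for the family Ile-AAT. With each clone centred on its median nuclear tRNA, chosen after the data were seen, the same 7 isodecoders differed and 0 families did. In DUS2L this difference was -4.94 for tRNA-Asn-GTT-8-1.

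In DUS3L clone #1, tRNA-Ile-AAT-3-1 (chromosome 6, 27275211 to 27275284), tRNA-Thr-CGT-3-1 (chromosome 6, 28648207 to 28648280) and tRNA-Asn-GTT-25-1 (chromosome 1, 149558419 to 149558493), chosen after their values were seen, fell from recovered levels of 1631, 1162 and 302 normalised counts to 39.8, 13.2 and 7.08, while clone #2 held 1890, 914 and 385. Reads moving to other isodecoders of the family would show there as a gain, and the others gained 7.51% ± 13.6 (SE) and 10.5% ± 26.4 of the reads lost by the chromosome 6 isodecoders, which argues against it for these. For tRNA-Asn-GTT-25-1 the gain was 61.1% ± 74.5, an error too large to decide. Loss of the chromosome 6 gene cluster is argued against by 32 single-copy isodecoders between these genes, whose median in clone #1 was -0.32, with 26 of them above -1. A change at single genes in that clone stays open and was not tested, nor was any effect of DUS3L loss, which both clones share.

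Many of the isodecoders called in both DUS2L clones may reflect a difference between library sets, since of 92 with a value in the needed tables, 74 (80.4%, 95% Wilson interval 71.2% to 87.3%) moved in the direction in which the wild type of the DUS3L table differs from the DUS1L knockouts (70.5% over all 224 isodecoders), both centred on the median nuclear isodecoder because the tables were scaled separately. The 74 were 26 of the 27 higher calls and 48 of the 65 lower ones. The share among the lower calls thus lay near that over all isodecoders, and the excess came mainly from the higher calls. With each DUS2L clone set against the recovered wild type of the DUS3L table and centred, 17 of 108 (15.7%, interval 10.1% to 23.8%) stayed past the threshold in the same direction in both clones and 10 passed in the opposite direction, while the SD across isodecoders was 1.27 and 1.34, against 2.47 and 2.61 with their own wild type. With their own wild type centred as well, 11 of 86 stayed and 6 passed in the opposite direction. Class II tRNAs called lower at the authors' scaling were an exception. Of the 15, 13 (86.7%, interval 62.1% to 96.3%) stayed lower, with medians of -2.44 and -2.78, which argues against that set difference as the whole cause for these. Of the 5 class II isodecoders called higher 0 stayed, with medians of 0.10 and -0.09. For the lower class II tRNAs loss of DUS2L stays open, as do a library set of the DUS2L clones' own and a size selection against the longer class II tRNAs, which were not tested. The E. coli tyrosine spike-in, which the knockout cannot alter, also fell in both DUS2L clones against their own wild type, at -0.92 and -1.88. The spike-ins for lysine and phenylalanine lay between -0.17 and 0.29. A cause outside the knockout is thus not excluded for these tRNAs. Over the 92, of which 19.6% moved against the set difference, loss of DUS2L and the library set cannot be told apart. The labels name wild-type sets 1 and 2 but do not say with which of them the DUS2L clone libraries were made. Because tRNAs are not independent, the intervals are lower limits of the spread.

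Of the 12 human anticodon families lower in both DUS2L clones, 3 stayed past the threshold in both after centring on the median nuclear family (25%, interval 8.89% to 53.2%) and 6 with the spike-ins as reference (50%, interval 25.4% to 74.6%). The first just met the bound for scaling as the cause, at most 25%, which was set before this result was seen. The second just met the bound against the choice of spike-ins, at least 50%. Both intervals reach past these bounds, so neither the authors' scaling nor the choice of spike-ins can be told apart from other sources of the fall. All 12 stayed below 0 in both clones after centring, with a median going from -1.83 to -0.73 in clone #1 (3 still called) and from -1.61 to -1.16 in clone #2 (6 still called). The errors stayed as before, so calls ended through the shift, as for Ala-TGC, which in the authors' deposited table was at -1.95 and -1.37 with a recovered SE of 0.53 in each clone and moved to -0.85 and -0.92. The count of 6 rests on the E. coli tyrosine spike-in, which the knockout cannot alter, and which passed in both clones of the authors' deposited table at -0.92 and -1.88, while those for lysine and phenylalanine lay between -0.17 and 0.29 and left all 12 families lower in both clones when they alone were the reference. Centring would also remove a true fall in the total of human tRNA, which stays open.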

How the results depend on the processing

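Centring on the median nuclear tRNA, the wild-type-free variance of clone differences, the filter on the wild-type comparison, families summed without isodecoders of low wild-type level, genes of 1 isodecoder name summed, spike-ins without tyrosine and the wild type of the DUS3L table for DUS2L were chosen after the data were seen. With an absolute log2 fold change of at least 1, all 18 counts stayed within 1.5 times. At an adjusted p under 0.01, isodecoders numbered 12 (from 23) in DUS1L clone #2, 3 (from 12) in both DUS1L clones and 14 (from 22) in DUS3L clone #1, and families 11 (from 25), 15 (from 30) and 8 (from 19) in DUS2L clone #1, clone #2 and both; a stricter threshold removes calls by construction. With a mean of at least 100, 18 isodecoders (from 33) passed in DUS3L clone #2, where fewer were tested, 4 lists (from 2) lay outside in DUS1L clone #2, and the correlations were 0.22 for DUS1L and DUS2L and 0.27 (from 0.18) for DUS1L and DUS3L. That filter also changed which lists lay outside in both DUS1L clones, from lysine, low, to leucine and class II, high: the lysine median of clone #1 turned to 0.30 and the class II median of clone #2 to 0.73. Of the other list medians in single clones, 5 came to lie outside and 5 no longer did. Centring turned the mitochondrial median of DUS2L clone #1 to 0.65. With spike-ins as reference, 16 families (from 25) passed in DUS2L clone #1, and after centring 1 family (from 2) passed in both DUS3L clones. With anticodon families, 3 lists (from 5) lay outside in DUS1L clone #1, 0 in DUS1L clone #2, 3 (from 6) in DUS2L clone #2 and 2 (from 4) in DUS3L clone #2, of 15 lists, and the correlations were -0.0454 for DUS1L and DUS2L and -0.00583 (from -0.15) for DUS2L and DUS3L. Without isodecoders of a wild-type level under 10, Tyr-GTA in DUS2L was at 0.10 and 1.21 (from 1.14 and 1.87), and the other named families moved by less than 1 SE. With the genes of its name summed, tRNA-Asn-GTT-9-2 in DUS3L was at 0.53 and 1.94 (from 2.90 and 4.11), and tRNA-Asn-GTT-9-1 in DUS2L moved by less than 1 SE. Without the shared wild-type spread, isodecoders differing between clones numbered 40 (from 0), 5 (from 1) and 33 (from 7) in DUS1L, DUS2L and DUS3L, and families 2, 1 (from 0 each) and 4 (from 1), as the smaller variance requires. The family in DUS2L was Tyr-ATA, whose recovered dispersion of 0 leaves counting error alone. With the clones also centred, isodecoders were 12, 6 and 30 and families 1, 2 and 7, and with the clones centred alone, 0 families (from 1) differed in DUS3L. Of 12 human families lower in both DUS2L clones, 3 stayed so after centring, 6 with all spike-ins as reference and 12 without the tyrosine spike-in. Against the wild type of the DUS3L table and centred, 17 isodecoders (from 108 at the authors' scaling) kept their call in both DUS2L clones. With their own wild type centred as well, 11 (from 86) did. Except where stated, the cause was not tested. Of named tRNAs in DUS2L clone #1, centring turned the E. coli lysine spike-in to 0.93 and the tyrosine spike-in to 0.17. It ended 16 other calls of named tRNAs in single clones and brought 3, spike-ins as reference ended 6, and a mean of at least 100 changed none of the 138 it covered. Not run, for want of values per library, were other size factors, total-count scaling, count models, no filter, pseudocounts, set tests with an estimated correlation and leaving out replicates. No paired analysis was possible because the columns carry no replicates. Depth per library is unknown, so what it limits cannot be given beyond the recovered errors.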

Other observations

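The groupings and values given here were chosen after the data were seen, and the calls are those at the authors' scaling, whose balance of higher and lower shifts with centring as given above. The isodecoders called in both DUS2L clones with a mean of at least 10 were set beside the rest by their share of their anticodon family. The 44 higher nuclear isodecoders made up a median of 2.01% of their family's mean count, the 68 lower ones 4.83%, and the 129 not called in both made up 9.49%. Of the 44, 6 belonged to a family called higher in both clones, and of the 68, 30 belonged to a family called lower. In 19 anticodon families, isodecoders called higher and called lower in both clones occurred together (12 families after centring on the median nuclear isodecoder, 15 with the spike-ins as reference), among them Ala-AGC with 4 and 4, Asn-GTT with 1 and 10 and Lys-CTT with 5 and 1. No test was run on these shares.

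tRNA-Gly-CCC-3-1 made up 0.00343% of human tRNA counts in the wild type of the DUS1L table and 0.576% in that of the DUS3L table. This difference was not tested, as the tables were scaled separately.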
